A study of Homo sapiens with 2 samples.

How the data were processed

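Gene expression was measured in the human colorectal cancer cell line HCT116 at 72 h after lentiviral infection at a multiplicity of infection of 20. One culture received a negative-control shRNA (shNC) and the other an shRNA against RAP1 (shRAP1), each hybridised to 1 array, so the 2 groups held 1 array each. Per the labels, total RNA was extracted with Trizol and amplified to biotin-labelled cRNA with an Affymetrix in vitro transcription kit that primes at the poly(A) tail. The deposited values are probe set intensity values on the linear scale, and the only tool named in the submitters' processing notes is RMA, which corrects background, normalises quantiles between arrays and summarises the probes of a probe set. The RMA software version and the set of arrays normalised together are not given in the sources used here. That the scale is linear was read from the values, which reached 25726 on both arrays. The planned comparison had assumed log2 values, so log2 was taken here with no pseudocount. Quantile normalisation removes any difference in total RNA per cell, so all differences are relative to the other genes on the array. Medians of the non-control probe sets were 77.0 on the shNC array and 78.9 on the shRAP1 array.

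Of 49293 non-control probe sets, 44988 carried 1 gene symbol in the platform annotation, 1832 carried several and 2473 carried none. A further 102 probe sets were array controls. No symbol needed updating through its gene identifier in the RefSeq table of assembly GRCh38.p14. That table was used for names and for the order of genes along chromosomes, and none of its coordinates are given because the build behind the array was not named. Probe sets with several symbols or none were not used for any gene. A probe set passed the floor where the higher of its 2 values reached the median of all non-control values, 78.0 on the linear scale or 6.29 on the log2 scale. Each gene was represented by its brightest probe set past the floor with a single symbol, which gave 10437 genes, 6135 of them with 2 or more such probe sets.

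All differences are shRAP1 minus shNC on the log2 scale. With 1 array per group there was no test, no p-value and no replicate check of any difference, and the number of arrays limits the precision. Genes were counted by a fixed size of 2-fold in either direction. The size of a difference was set beside the SD of the differences of the 501 genes nearest in mean value, which describes the spread between genes on these arrays and not an experimental error. The grouping, lists, naming rule and most alternatives were fixed before the data were examined. The naming rule took TERF2IP, RAP1A and RAP1B, then up to 14 genes per direction past 2-fold with all probe sets past the floor moving the same way. It also took up to 4 members of each list with the largest difference in size, and the control probe sets. Of 59 such list members with 2 or more probe sets past the floor, 5 had probe sets of both signs.

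The 25 fixed lists covered telomere end protection, RAP1 GTPases and their regulators, NF-kB targets, p53 targets, G1/S and DNA replication, G2/M and mitosis, interferon-stimulated genes, the unfolded protein response with ATF4 targets, cholesterol synthesis and uptake, glycolysis and hypoxia response, fatty acid oxidation, oxidative phosphorylation, Wnt/beta-catenin targets, MAPK output, epithelial genes, mesenchymal genes, integrins and focal adhesion, DNA repair, BCL2 family and apoptosis, heat shock chaperones, NRF2 targets, RNA interference machinery, ribosomal proteins, leukocyte markers, and fibroblast and endothelial markers. For lists with at least 5 measured members, the median difference was placed among 10000 random gene lists of the same size matched on mean value in 20 bins. The percentile describes these 2 arrays and is not a p-value, since list members are co-regulated. Intervals of a median are 95% order-statistic intervals over its member genes, and they do not include variation between cultures. Values were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and plots were drawn with matplotlib 3.10.9.

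The computation was checked on simulated data for this comparison with 10437 genes. All 200 genes planted at 1.5 on the log2 scale were counted at the 2-fold size and 0 others were. Of 40 unshifted random lists, 39 fell in the central 95%, and a list shifted by −0.1 moved from percentile 30.8 to 0.01. The simulated genes varied independently, with the spread seen at their brightness. The planted size lay far past the 2-fold size relative to that spread, so those counts were all but fixed in advance. How lists of co-regulated genes behave was not simulated. Alternatives changed the rule from probe sets to genes, the floor, the probe sets admitted, the size counted, the centring (a lowess trend with a span of 0.3), the summary of a list and the number of bins. Probe sets with names ending in _x_at or _s_at, which can match related transcripts, were left out in one alternative.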

Results

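The data were 2 arrays of HCT116 cells, an epithelial line from a colorectal carcinoma, 1 from cells given a negative-control shRNA (shNC) and 1 from cells given a single shRNA against RAP1 (shRAP1). The stated question was how RAP1 affects colorectal cancer cells. The 2 arrays were close to each other, with a Pearson correlation of 0.997 across probe sets on the log2 scale. Differences of the 10437 measured genes had an SD of 0.16, and 95% of them lay between −0.29 and 0.32. Among 6135 genes with 2 or more probe sets, the differences of 2 probe sets of a gene correlated at 0.622 across genes, which are not independent replicates.

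The name RAP1 can stand for TERF2IP, a shelterin protein bound at telomeres, or for the small GTPase genes RAP1A and RAP1B. The TERF2IP signal was 1311 in shNC and 624 in shRAP1, a level of 47.6% of the control. This difference of −1.07 was the lowest but one among 10437 genes and 7.44 times the SD of genes of similar brightness in size. It rested on a single probe set, whose name ends in _s_at, the mark of probes that can match more than one transcript. For RAP1A, the 3 probe sets past the floor differed by −0.18, −0.23 and −0.21, and the brightest stood at 88.0% of the control. For RAP1B, the 2 single-symbol probe sets past the floor differed by −0.10 and −0.15. The brightest stood at 93.3% of the control, a difference 0.70 times the SD of such genes in size. Probe sets past the floor that carry both RAP1B and RAP1BL, which were not used for any gene, differed by −0.15 and −0.22.

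**Figure D1:**
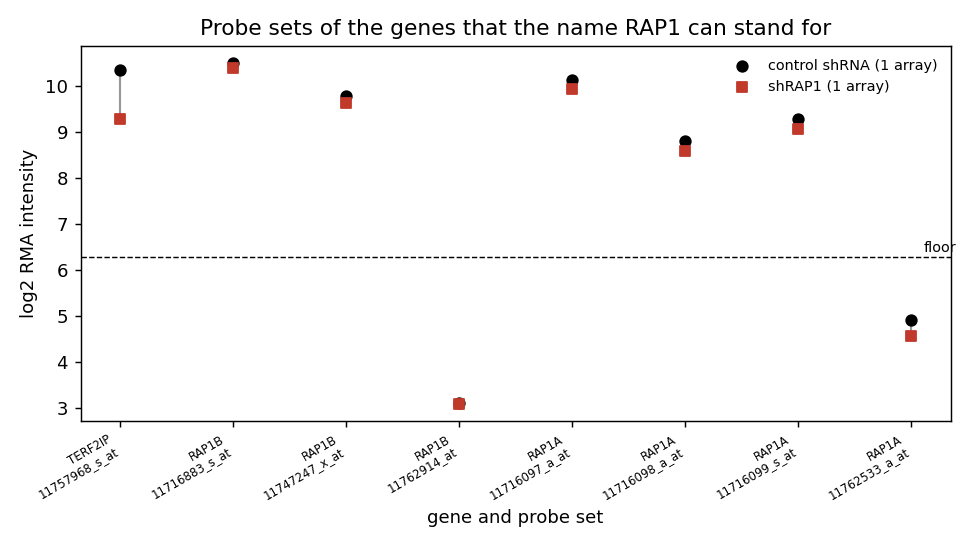
Log2 RMA intensity (y axis) of every single-symbol probe set of TERF2IP, RAP1B and RAP1A (x axis) on the shNC array (black circles) and the shRAP1 array (red squares), with the floor as a dashed line. The TERF2IP probe set was 1.07 lower in shRAP1, while the RAP1A and RAP1B probe sets past the floor were 0.10 to 0.23 lower.

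Besides TERF2IP, 3 genes differed by 2-fold or more. RUNX2, a transcription factor of osteoblast differentiation, was 2.35-fold higher in shRAP1 (7.16 in shNC and 8.40 in shRAP1 on the log2 scale). EGR3, an immediate early zinc finger transcription factor, was 2.20-fold higher (6.85 and 7.99). TNFSF18, the ligand of the GITR receptor, was lower by a difference of −1.36 (6.89 and 5.53). Its shRAP1 value, 46.1 on the linear scale, lay below the floor of 78.0, so the size of this difference is uncertain. Against the floor itself the TNFSF18 difference would not reach 2-fold. In total 2 genes were higher and 2 lower by this size, each on 1 probe set past the floor. The dimmer probe sets below the floor differed by 0.48 for RUNX2, by 0.07, −0.20 and −0.10 for EGR3, and by −0.26 for TNFSF18.

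At the smaller size of 1.5-fold, 22 genes were higher and 18 lower in shRAP1, and for 6 higher and 6 lower genes 2 or more probe sets past the floor moved the same way. Several of the counted genes had 1 value below the floor, among them TENM3, TSPAN18 and PPIL6 in shNC. CCL20, CCN2 and LINC01588 had such a value in shRAP1, so the sizes of these differences are uncertain. The genes named here were chosen after their values were seen. Among the higher genes, CXADR, the receptor for coxsackievirus and adenovirus, differed by 0.74 with 4 probe sets between 0.37 and 0.74. DPP4, a cell surface peptidase, differed by 0.74 and 0.70 on its 2 probe sets, and PLPP3, a lipid phosphatase, by 0.70 on both of those past the floor. FOXQ1, a forkhead transcription factor, differed by 0.98 on its 1 probe set past the floor, with its shNC value below it. Among the lower genes, CYP24A1, the enzyme that inactivates vitamin D, differed by −0.69 with 3 probe sets between −0.82 and −0.69. NMI, an interferon-inducible protein, differed by −0.61 with 5 probe sets between −0.61 and −0.45. EIF3J, a translation initiation factor subunit, differed by −0.75 and −0.38 on 2 probe sets. DHRS2, a short-chain dehydrogenase, differed by −0.95 on 1 probe set.

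**Figure D2:**
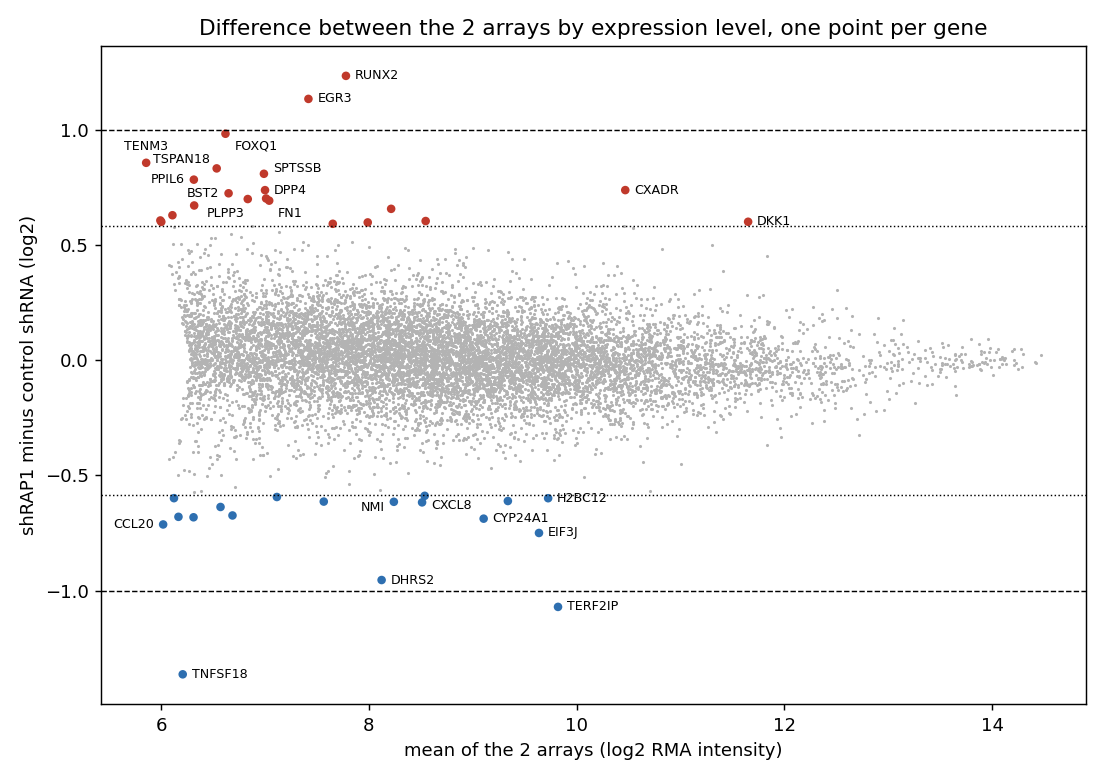
Difference between the arrays (shRAP1 minus shNC, log2, y axis) against the mean of the 2 arrays (log2 RMA intensity, x axis) for 10437 genes, with dashed lines at 2-fold and dotted lines at 1.5-fold. The 22 genes at least 1.5-fold higher are red and the 18 at least 1.5-fold lower are blue, some of them labelled, with RUNX2 at 1.24, TERF2IP at −1.07 and TNFSF18, below the floor in shRAP1, at −1.36.

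Genes of the cell cycle were lower in shRAP1 by small amounts. Of 37 measured G1/S and DNA replication genes, 29 were lower and 8 higher, with a median of −0.13 (95% interval −0.18 to −0.056) at percentile 0 of matched random lists. GINS2, a subunit of the replicative helicase complex, differed by −0.49 on 1 probe set, the thymidine kinase TK1 by −0.45, and the flap endonuclease FEN1 by −0.33. Of the higher members, named after their values were seen, GINS1 was at 0.15 with its other probe set at 0.45. MCM7 was at 0.13 with 4 probe sets between 0.062 and 0.13. Of 39 G2/M and mitosis genes, 32 were lower and 7 higher, with a median of −0.096 (−0.14 to −0.062) at percentile 0.02. The kinetochore genes NUF2 and NDC80 differed by −0.44 and −0.30, the chromokinesin KIF4A by −0.37 with its other probe set at −0.039, and the mitotic transcription factor FOXM1 by −0.30. Also named after their values were seen, TOP2A was at 0.14 with 3 probe sets between −0.22 and 0.14. MKI67 was at 0.075 with 6 probe sets between −0.13 and 0.20. Of 31 DNA repair genes, 22 were lower and 9 higher, with a median of −0.050 (−0.13 to −0.0050) at percentile 2.25. RAD51C, a recombination factor, differed by −0.34, and PARP1 and XRCC6, which bind DNA breaks, by −0.33 each. The DNA repair list lay inside the central 95% of random lists with no floor and without the less specific probe sets.

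Interferon and NF-kB target genes were also lower on balance. Of 24 measured interferon-stimulated genes, 19 were lower and 5 higher, with a median of −0.11 (−0.23 to −0.032) at percentile 0.01. IFIT1 and IFIT2, which bind foreign RNA or restrict its translation, differed by −0.59 and −0.50, and SAMD9 by −0.43. The shRAP1 value of IFIT2 was below the floor. BST2, which tethers budding virus to the cell surface, went the other way at 0.73, with 2 probe sets at 0.73 and 0.61. Their shNC values, 6.29 and 6.19 on the log2 scale, lay near the floor. The other higher members were IFITM1 at 0.42 with 2 probe sets at 0.42 and 0.47, IFITM3 at 0.17 and IRF1 at 0.062. OAS2 was higher by 0.33 from an shNC value below the floor. Of 17 NF-kB target genes, 13 were lower and 4 higher, with a median of −0.068 (−0.13 to −0.0016) at percentile 1.58. The chemokines led this list, with CCL20 at −0.71, CXCL8 at −0.62 and CXCL1 at −0.38 (−0.092 on its other probe set), while the NF-kB subunit gene NFKB2 was at 0.15. The shRAP1 value of CCL20 was below the floor. With the floor at the 75th percentile of all values, the NF-kB list lay inside the central 95%.

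Lists of protein folding, redox and metabolic genes stood lower too. Of 32 unfolded protein response and ATF4 target genes, 24 were lower, with a median of −0.088 (−0.15 to −0.024) at percentile 0.06. Its leading members were the co-chaperone gene DNAJC3 at −0.39 with its other probe set past the floor at −0.013, the transcription factor XBP1 at −0.34 and PHGDH, the first enzyme of serine synthesis, at −0.31. Of 19 heat shock chaperone genes, 13 were lower, with a median of −0.12 (−0.21 to 0.053) at percentile 0.06. CHORDC1, a partner of HSP90, differed by −0.57 with 6 probe sets between −0.91 and −0.36, and HSP90AA1 by −0.26. Of 20 NRF2 targets, 15 were lower, with a median of −0.098 (−0.18 to −0.00062) at percentile 0.19. GCLM, of glutathione synthesis, was at −0.34, HMOX1, of haem breakdown, at −0.29 with 3 probe sets between −0.29 and 0.00087, and the transporter ABCC3 at 0.29 and 0.088 on its 2 probe sets. This list lay inside the central 95% with no floor and with the higher floor. Of 17 cholesterol genes, 13 were lower, with a median of −0.092 (−0.17 to −0.033) at percentile 0.96, led by the mevalonate pathway genes IDI1 at −0.36, HMGCS1 at −0.34 and FDPS at −0.33. Of 31 oxidative phosphorylation subunits, 27 were lower, with a median of −0.071 (−0.13 to −0.025) at percentile 0.56, among them NDUFV2 of complex I at −0.27 and SDHD of complex II at −0.20. Part of this median was shared with genes of similar brightness, as the central 95% of matched random lists ran from −0.053 to 0.024. With lowess centring the median of the oxidative phosphorylation list was −0.046 at percentile 0.46. That list lay inside the central 95% when a gene was the median of all its probe sets.

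Higher on balance were the combined lists of glycolysis with hypoxia-response genes and of MAPK output with immediate early genes. The lists of Wnt targets and adhesion genes also stood higher. Of 29 glycolysis and hypoxia-response genes, 20 were higher and 9 lower, with a median of 0.077 (−0.0074 to 0.20) at percentile 99.9. The aldolase gene ALDOC differed by 0.39 with 5 probe sets between 0.095 and 0.39, PFKFB4, a regulator of glycolytic flux, by 0.33, NDRG1 by 0.30 with all 6 probe sets higher, and the pyruvate dehydrogenase kinase PDK1 by 0.27. The glycolytic enzymes did not move together, and 8 of the 9 lower members were among them. With lowess centring, a check chosen after seeing the data, 3 of these 8 (GPI, PGAM1 and PKM) turned slightly positive. Chosen after the values were seen, the enzyme genes TPI1 and PGK1 differed by −0.21 and −0.17, with 3 and 9 probe sets that were all lower. Of 26 MAPK output and immediate early genes, 16 were higher and 10 lower, with a median of 0.067 (−0.017 to 0.17) at percentile 99.5. The MAPK phosphatase DUSP4 differed by 0.58, EGR1 by 0.50 with 6 probe sets between 0.37 and 0.54, FOSL1, of the AP-1 family, by 0.34 with 6 probe sets between 0.076 and 0.37, and the cyclin gene CCND1 by −0.33 with 4 probe sets between −0.37 and −0.067. Members of this list, named after their values were seen, did not move together. JUN, JUNB and FOS were at 0.22, 0.24 and 0.20, and ATF3 at −0.30. DUSP5, DUSP6 and DUSP1 were at 0.22, −0.016 and −0.0075. SPRY2 and SPRY4 were at −0.22 and 0.046, and SPRED1 and SPRED2 at −0.064 and 0.0047. Of 12 Wnt/beta-catenin targets, 9 were higher and 3 lower, with a median of 0.12 (−0.13 to 0.30) at percentile 99.5. The Wnt antagonist DKK1 differed by 0.60, and the negative regulators NKD1 and RNF43 by 0.31 and 0.30. CCND1 is also a member of the Wnt list, which lay inside the central 95% with no floor.

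Of 25 integrin and focal adhesion genes, 16 were higher and 9 lower, with a median of 0.077 (−0.019 to 0.15) at percentile 99.8, and this list left the upper tail under 5 of 8 alternatives. The laminin-binding integrin subunit ITGB4 differed by 0.34 with 8 probe sets between 0.13 and 0.47, and the subunit ITGAV by −0.28 with 4 probe sets between −0.45 and −0.055. Of 22 genes of the RAP1 GTPases, their exchange factors, GTPase-activating proteins and effectors, 14 were higher and 8 lower, with a median of 0.088 (−0.022 to 0.14) at percentile 98.8. The GTPase-activating protein genes SIPA1L2 and SIPA1L1 differed by 0.34 and 0.20, the exchange factor RAPGEF2 by 0.20, and talin, TLN1, by −0.21. The other probe set past the floor was at 0.042 for TLN1 and at 0.029 for SIPA1L1. This list kept its place above the central 95% in 5 of 8 alternatives, and lost it with the higher floor, the lowess-centred differences and the mean.

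The remaining lists lay inside the central 95% of random lists with the main settings, or had too few measured members for a percentile. Of 21 telomere genes, 12 were higher and 9 lower, with a median of 0.016 at percentile 62.0 and a mean of −0.041, and after TERF2IP the largest sizes were TNKS2, a tankyrase, at 0.48, DKC1, of the telomerase complex, at −0.23 and STN1 at 0.22. Of 27 p53 targets, 17 were lower, with a median of −0.047 at percentile 4.32, among them TP53I3 at −0.44, ZMAT3 at 0.28 and 0.072 on its 2 probe sets, and FAS at −0.25. Fatty acid oxidation genes had a median of 0.031 at percentile 76.5, with PPARG at 0.47, and BCL2 family and apoptosis genes 0.034 at percentile 84.2, with BMF at 0.49 from an shNC value below the floor. Epithelial genes had a median of −0.026 at percentile 17.3, with CEACAM6 at −0.21. Mesenchymal genes had a median of 0.081 at percentile 89.8, with the matrix protein fibronectin, FN1, at 0.69 on 4 probe sets between 0.41 and 0.69 and the matricellular gene CCN2 at −0.68 to an shRAP1 value below the floor. Without probe sets ending in _x_at or _s_at, the mesenchymal list had a median of 0.14 at percentile 99.0, above the central 95%. RNA interference genes had a median of −0.020 at percentile 14.8, which was above 0 under 5 of 8 alternatives, with AGO2, which cuts the targets of small RNAs, at 0.60. The 33 ribosomal protein genes had a median of 0 at percentile 89.9, and RPL7, the member with the largest size, was at −0.13. Of the leukocyte markers 4 were measured, with HLA-DRA at 0.29 and a median of 0.13, and of the fibroblast and endothelial markers 3, with KDR at 0.15 and a median of 0.096.

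**Figure D3:**
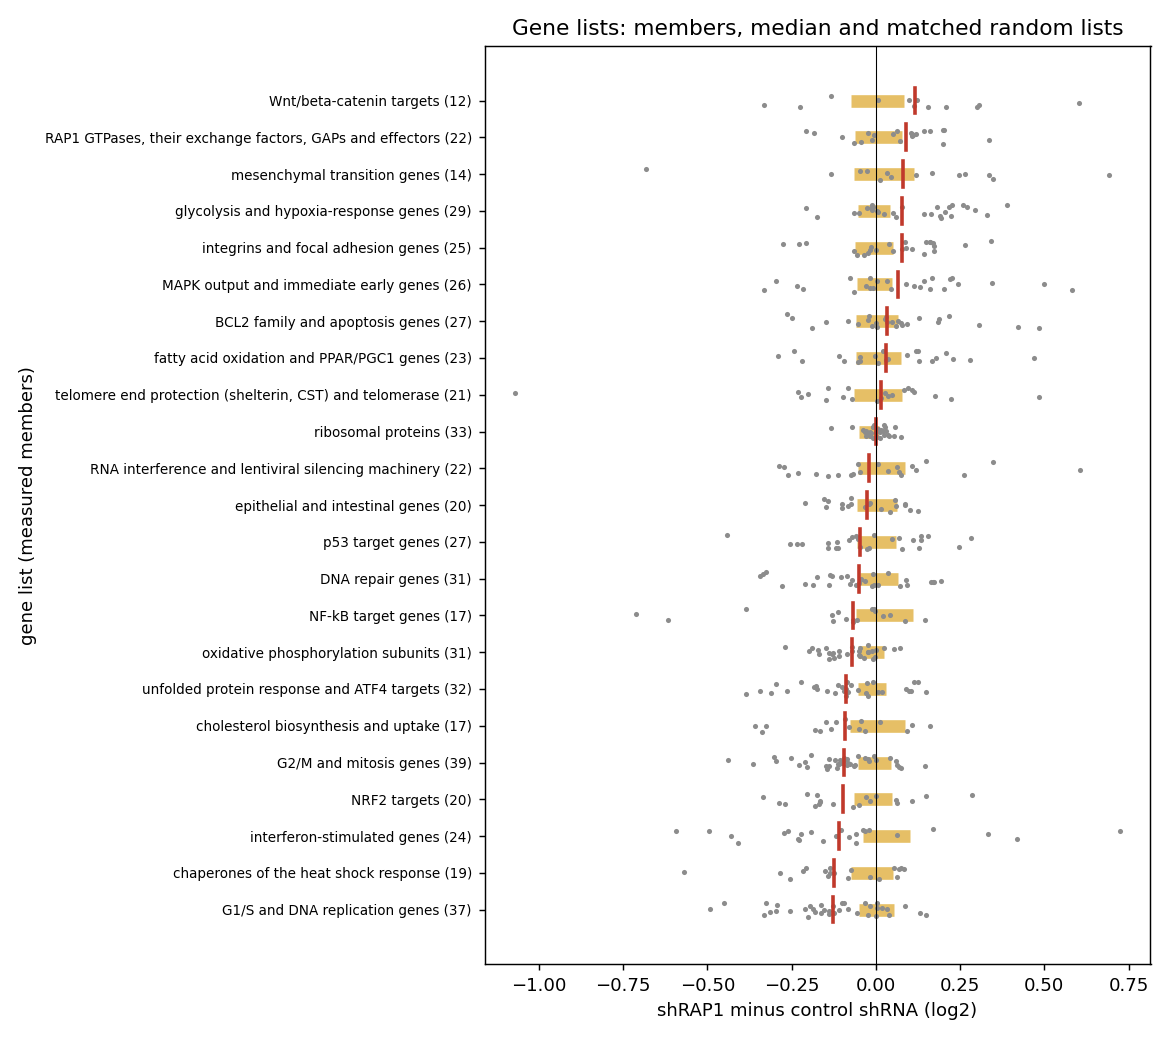
Differences (shRAP1 minus shNC, log2, x axis) of the measured members (grey points) of each fixed list with at least 5 of them (y axis, number measured in brackets), with the list median as a red line and the central 95% of the medians of matched random lists as a yellow band. The medians ran from −0.13 for G1/S and DNA replication genes to 0.12 for Wnt/beta-catenin targets.

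Each difference above compares 1 culture with 1 culture and has no replicate check. On the control probe sets, the polyadenylated spike-ins dap, lys and phe had medians of −0.30, −0.41 and −0.29 and thr a median of 0.41, while the hybridisation controls lay between −0.087 and 0.095. Background probe sets with a GC content class of 16 to 25 were all higher in shRAP1 (10 of 10, median 0.11), against 3 of 13 in classes 3 to 15 (median −0.025). The 3′ minus 5′ signal was −0.024 in shNC and −0.029 in shRAP1 for GAPDH, and 1.11 and 1.10 for ACTB. On the spike-ins, the 5′ probe sets of lys differed by −0.59 and −0.58 and the 3′ ones by −0.31 and −0.18. For dap the 5′ values were −0.34 and −0.38 and the 3′ values −0.28 and −0.24. Those of phe were −0.24 and −0.34 against −0.20 and −0.21, and those of thr 0.39 and 0.47 against 0.43 and 0.39. The cause of these 5′ and 3′ differences was not tested.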

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

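A probe set with no gene name in the annotation used here was 2.67-fold higher in shRAP1, with 6.31 in shNC and 7.73 in shRAP1 on the log2 scale. Its difference of 1.42 exceeded that of any named gene past the floor, and it stood out because it lay outside the gene-level comparison.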

How the results depend on the processing

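Each result was recomputed under other settings, of which 1, that all probe sets of a gene agree below the floor too, was chosen after seeing the data. Of 242 values, 13 left the interval, spread or 1.5-fold range set around the main value. The sign changed for 8 values of 3 lists, which lay inside the central 95% of random lists or had no percentile: telomere genes (to −0.026 and −0.041), RNA interference genes (to between 0.0029 and 0.023) and the fibroblast and endothelial markers. The count of genes at least 2-fold higher (2) was 0 with the median of all probe sets, 1 with the floor at the 75th percentile, 0 among genes with 2 or more agreeing probe sets, 1 where all probe sets had to agree and 22 at 1.5-fold. The count at least 2-fold lower (2) was 1, 1, 0, 2 and 18 in the same order, 1 without probe sets ending in _x_at or _s_at and 3 with no floor. Leaving those probe sets out gave no value for TERF2IP, whose only probe set ends in _s_at. Of 198 list medians, 196 stayed inside the main value's interval, which was wide for some lists, such as p53 targets at −0.047 (percentile 4.32) and at −0.0070 (50.9) with the median of all probe sets. The exceptions were ribosomal proteins at 0.023 with lowess centring and the fibroblast and endothelial markers at −0.048 with the median of all probe sets. The median of genes near chromosome ends was 0.0096 with the higher floor. Of the 10 lists below the central 95% of random lists, 6 stayed there under all 8 alternatives (both cell cycle lists, interferon, unfolded protein response, cholesterol, chaperones), and of the 5 above it 2 did (glycolysis and hypoxia response, MAPK output). Of the 8 inside, 1 (mesenchymal) left it, at 0.14 without probe sets ending in _x_at or _s_at. The causes of these moves were not tested. No paired analysis was possible because each group had 1 array. How far signal over background limits genes near the floor was not tested, as the floor itself admits genes of low mean value only where the difference is large.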

Other observations

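Of the tests in this part, those of the culture, the off-target effect, the base composition of transcripts, the spike-ins, the NF-kB list without CX3CL1, the ends of AT-rich chromosomes and the histone genes were chosen or altered only after the result was seen.

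Several replication-dependent histone genes were among the lower genes in shRAP1. Labelling primed at the poly(A) tail, so these values describe polyadenylated transcripts of the genes and not their total mRNA. The probe sets of H1-2, H2AC6, H2AC25, H3C8 and H4C3 end in _x_at or _s_at and can match related transcripts. H3C4 differed by −0.68, H2BC12 by −0.60, H2AC6 by −0.60, H1-2 by −0.39 and H2BC5 by −0.37, while H2AC20 was at 0.36. The shRAP1 values of H3C4 and H2AC6 were below the floor. A further probe set of H2BC12, below the floor on both arrays, was at 0.088. Of the 10 measured cluster genes 8 were lower, with a median of −0.24 at percentile 0 of matched random lists. These genes were noticed because 3 of them passed 1.5-fold, so the percentile of the family is not independent of how it was found. The other 7 had a median of −0.068 at percentile 7.75, but taking out the largest differences draws this median toward 0, so it decides nothing about a shift of the whole family.

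Whether the NF-kB list stood low mainly through the chemokines CCL20, CXCL8, CXCL1 and CXCL2 could not be decided. Without these, the 13 remaining genes had a median of −0.011 at percentile 24.0 of matched random lists, with 9 lower. All of the genes taken out lay below the list median, so the median of the rest had to rise. The result therefore does not show that the shift was particular to chemokines. Without the chemokine CX3CL1 as well, which was itself at −0.011, the other 12 genes had a median of −0.030 at percentile 14.5, with 8 lower. A smaller shift of these genes is not excluded.

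The lower cell cycle lists held 76 genes with a median of −0.11. The values argue against an intensity-dependent trend as the whole cause, since the joint median was −0.091 after lowess correction (percentile 0), and against a regional trend, since the 712 chromosomal neighbours of the genes had a median of 0.0096, where a gene and its neighbours correlated at 0.123 over 10429 genes. What stays open is the base composition of the transcripts, as GC-rich background probe sets were higher by 0.11 and transcript sequences were not used here. With 1 culture per group and 1 shRNA against RAP1, slower proliferation after loss of the target, an off-target effect of the shRNA and a difference between cultures, such as density, cannot be told apart, and each could account for the pattern. The target, an off-target effect and the culture are as little separated for the other differences between these arrays. Base composition of the transcripts was not tested for the other lists either and stays open for them too.

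The polyadenylated spike-ins, added to the RNA before labelling, moved apart between the arrays. Different amounts of sample RNA per spike-in would move all of them one way, but the lowest thr probe set lay 0.564 above the highest dap, lys or phe probe set. Unequal hybridisation would move the controls added after labelling as well, whose median size of difference was 0.026 against 0.362 for the spike-ins. The source of the split was not found, and no biological explanation was tested.

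Since TERF2IP binds telomeres, genes near chromosome ends were examined by their order along the chromosomes. The outermost 25 measured genes of each end, 1025 in all, had a median of 0.032 (95% interval 0.021 to 0.045) at percentile 100 of matched random lists, 0.024 above all other genes. The end genes form blocks of neighbours, while the random lists held scattered genes and the interval treats genes as independent. Since a gene and its neighbours correlated at 0.123, the percentiles and the interval can overstate how unusual these medians were. With the floor at the 75th percentile of all values, the median was 0.0096, still at percentile 100, and the outermost 10 had 0.026 at percentile 93.6. Release of these genes could give such a shift, but so could regional base composition, because interior genes of the GC-rich chromosomes 16, 17, 19 and 22 exceeded those of the AT-rich chromosomes 3, 4, 5 and 13 by 0.043, more than the excess at the ends. The 175 end genes of those AT-rich chromosomes had a median of 0.0078, 0.019 above their interior at percentile 87.7. That excess was similar in size but not resolved, so release and base composition were not separated.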
